A study of Rattus norvegicus with 8 samples.

How the data were processed

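Total RNA from purified Sertoli cells, spermatogonia, pachytene spermatocytes and round spermatids was depleted of ribosomal RNA, fragmented and copied with random primers into libraries that do not mark strand, per the labels' protocols. Each library was loaded in 2 lanes, per the same protocols. The submitters' processing notes name TopHat 1.4.1, Cufflinks 1.2.0, Cuffdiff, bedtools 2.12.0 and the rat assembly rn4, without roles or order. How reads with several alignments were treated is not given in the sources used here.

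Deposited files of 3 kinds were used. The expression table holds log2 values of FPKM for 99438 transfrags in 8 samples, quantile-normalized by the authors, per its name. Its lowest value, -4.322, is the log2 of 0.05 and fills 24.7% to 48.2% of each column. The combined assembly gives the exons of each transfrag, its locus, the nearest reference gene and a class code, per the file's attributes. The coverage signal of the deposited tracks is the whole-number depth of mapped reads at each position, not scaled to library size. Isolated stretches of coverage summed to 60 bases (1 read) in 10.5% to 16.5% of cases and to 120 bases (2 reads) in 41.6% to 49.3%, from which reads of 60 bases in pairs were inferred and 120 bases of coverage were counted as 1 fragment. Quantile normalization gives every sample the same distribution, so it hides any change in total RNA and can shift the balance of rises and falls. All 8 columns were assigned to samples by name.

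The 2 samples of a cell type were compared first, through fragments summed over the merged exons of each locus. Over loci of 25 to 5000 fragments their variance was 0.957, 0.980, 0.997 and 0.972 times that of sampling. Above 5000 fragments it was 8.93, 14.7, 3.26 and 10.2 times that of sampling, with a standard deviation of the log2 ratio of at most 0.0611. By a rule set before the data were examined they were counted as 1 sample, no p-value was computed, and the planned limma and Fisher tests were replaced by a rule of size. The unit compared was log2(FPKM + 1), a scale that understates changes of weak transcripts. Transfrags entered with at least 1 FPKM in both lanes of 1 cell type, and a difference of lane means of 2 or more (4-fold) was a call. A null of the same spread swapped 1 lane of each cell type between the groups compared.

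Gene values came from 1 transfrag per symbol: that of the annotated class with the highest mean, or else a new isoform. The 15 gene lists (Sertoli, spermatogonial, Leydig, peritubular myoid, macrophage and leukocyte, endothelial and erythroid markers, and meiotic prophase, pachytene-to-spermatid, spermatid, flagellar axoneme, piRNA pathway, mitotic cell cycle, cholesterol and steroid synthesis and extracellular matrix genes) were fixed before the data were examined. Mybl1 and Piwil1 stand on 2 of them. A list's median was placed among 10000 random lists of the same size, matched on mean level in 20 bins. Genes named in the text are, per comparison, the 8 annotated symbols with the largest rise and the 8 with the largest fall (ranked with values under 1 FPKM set to 1, both lanes apart, gene models without a name left out), the 3 members of each list with the largest difference, and 13 fixed marker genes. Of the genes so chosen 2 are not reported here. Inha, the only Sertoli marker that rose in the first comparison, was added after its values were seen, as were the differences of Tbpl1, Tf and Tex12 that changed sign when transfrags were summed. Of those markers Sox9 had no transfrag of the classes used. Symbols were read from the assembly. The RefSeq gene table of assembly GRCr8 was used for synonyms only.

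Alternatives were a pseudocount of 0.1, no filter, a filter at the table's median (-1.00 on the log2 scale), 1 value per locus, values recomputed from the tracks as fragments scaled to exon length and to the sample's exonic fragments without chrUn and chrM, call thresholds of 1 and 4, and each lane left out. Leaving out chrUn and chrM, and transfrags of 1 exon, was added after the data were seen. The calling rule and the list percentile were tested on simulated data made from spermatogonia against spermatogonia over 99438 transfrags. Of 100 transfrags changed by 3 on the log2 scale 99% were called, of 100 changed by 1 none, and 46 unchanged ones were. The null from swapped lanes gave more calls among the 80440 transfrags compared, at 389, 226 and 393 in the 3 comparisons. The simulated count of 46 may therefore understate false calls, and the 99% may be too high. Of 100 random lists 6 lay outside the central 95% of percentiles.

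Depth per lane was 15685658 to 19009096 fragments. Of mapped bases 47.4% to 70.5% lay on chrUn and 0.450% to 1.82% on chrM. Of the remaining bases 57.3%, 57.1%, 79.9% and 75.4% lay in assembled exons in Sertoli cells, spermatogonia, pachytene spermatocytes and round spermatids. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.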

Results

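RNA was sequenced from 4 testicular cell types of Sprague-Dawley rats, a laboratory strain, to follow transcription, including regions outside annotated genes, through the formation of sperm. Sertoli cells, the somatic cells that nurse the germ cells, came from rats 20 days old. Spermatogonia, the mitotic germ cells, came from rats 9 days old. Pachytene spermatocytes, germ cells in the prophase of the first meiotic division, and round spermatids, the haploid cells that follow meiosis, both came from adults of 90 days. Age and cell type therefore change together in every comparison except the last. Each cell type had 2 samples. Their fragments in the tracks, summed per locus, differed by no more than sampling over loci of 25 to 5000 fragments. Their variance was 0.957 times that of sampling in Sertoli cells, 0.980 in spermatogonia, 0.997 in pachytene spermatocytes and 0.972 in round spermatids. The same ratio between neighbouring cell types was 30.7, 206 and 320. The 2 samples were therefore counted as 2 lanes of 1 library, so n = 1 per cell type and no p-value is given. The deposited transfrag values, on which most results below rest, agreed less well between lanes. Their Pearson correlation on the log2 scale was 0.853 in Sertoli cells, 0.842 in spermatogonia, 0.841 in pachytene spermatocytes and 0.698 in round spermatids. Values below are means of the 2 lanes, and ranges in parentheses span the 4 pairings of lanes. They cover technical error only.

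Each lane held the equivalent of 31371317 to 38018193 mapped reads of 60 bases. After the unplaced sequence (chrUn) and the mitochondrial genome (chrM) were set aside, assembled exons held 3925269 fragments per lane in Sertoli cells and 3958378 in spermatogonia. Pachytene spermatocytes held 6762743 and round spermatids 4200333. Loci with at least 10 fragments numbered 20709 in Sertoli cells, 19492 in spermatogonia, 16165 in pachytene spermatocytes and 11918 in round spermatids, averaged over lanes. The 10 loci of highest coverage took 10.9%, 14.9%, 6.27% and 19.1% of exonic fragments in that order. Of 99438 assembled transcript fragments (transfrags), 80440 reached 1 FPKM in both lanes of at least 1 cell type and were compared. A transfrag was called when 2 cell types differed by at least 2 on the log2(FPKM + 1) scale, which is 4-fold at high levels and more at low ones. By this rule 44392 transfrags differed between some pair of cell types. The highest level was in Sertoli cells for 11312 of them, in spermatogonia for 10170, in pachytene spermatocytes for 11645 and in round spermatids for 11265. This near-equal split depended on how the values were computed, since values recomputed from the coverage tracks gave 21281, 20101, 15048 and 8176 in that order. The track values differ from the deposited ones in both quantification and normalization, so the split cannot be assigned to either.

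**Figure D1:**
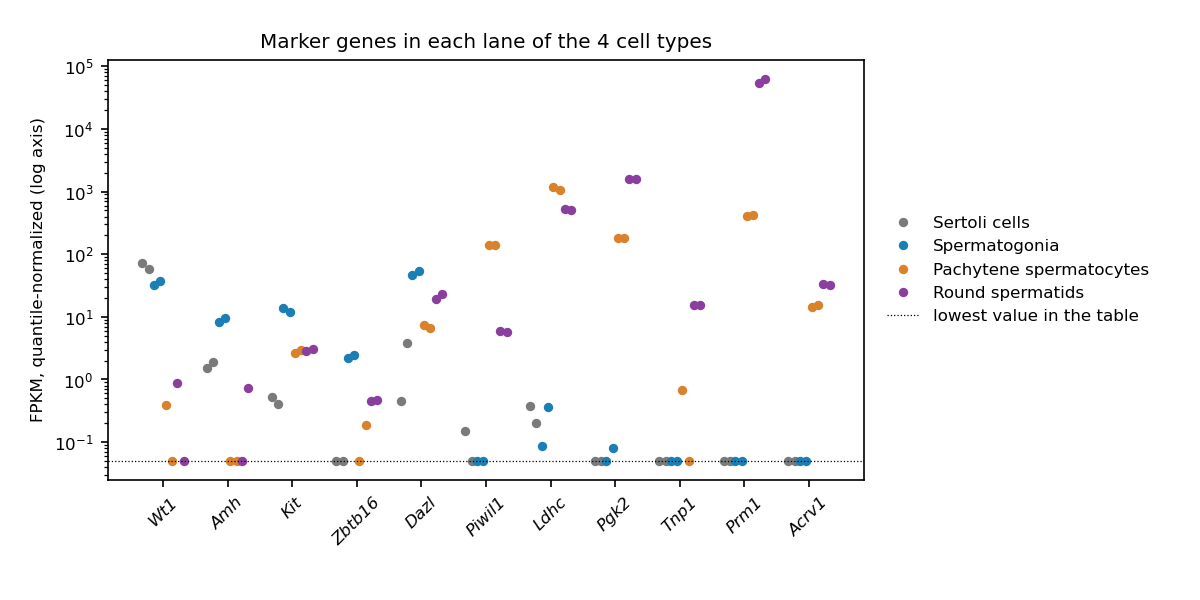
Quantile-normalized FPKM (log axis) of 11 marker genes in each lane of the 4 cell types, with 1 point per lane and the lowest value of the table as a dotted line. Prm1 stood at 58518 FPKM in round spermatids and Wt1 at 65.8 FPKM in Sertoli cells, as lane means.

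The first comparison set spermatogonia against Sertoli cells, a germ cell against its somatic neighbour. Medians of the spermatogonial, piRNA pathway and meiotic prophase lists were higher in the spermatogonial preparation than those of nearly all matched random lists, though most members of each list were not called. Tex15, needed for meiotic recombination and transposon silencing, rose by 5.15 (5.05 to 5.26) to 39.5 FPKM. The RNA-binding germ cell gene Dazl rose by 4.28 (3.33 to 5.24) to 50.3 FPKM. The largest fall of an annotated gene was that of A2m, a protease inhibitor (-6.37, -6.46 to -6.28). Tagln, the smooth muscle protein transgelin, differed by -5.05 (-5.06 to -5.04). In all, 2975 transfrags rose and 3150 fell, and 1498 and 1636 of them did so in every pairing of lanes. A null of the same spread, made from lane differences, gave 389 calls.

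Among annotated genes the largest rises also included Crabp1, which binds retinoic acid (5.36, to 49.1 FPKM), Apoe, a lipid carrier (5.07, to 40.6 FPKM), and Fcrla, an Fc receptor-like protein (5.55, to 56.8 FPKM). The alpha-tubulin genes Tuba3a and Tuba3b rose by 5.60 and 5.59. They are near-identical copies, so the split of reads between them is uncertain. Clk1, a kinase of splicing factors, rose by 4.58 in its annotated transfrag and by 1.43 when its transfrags were summed, under the 4-fold rule. The other large falls were Mustn1 (-5.82), Testin, a protein secreted by Sertoli cells (-5.84), the phospholipid-binding annexin Anxa3 (-5.94), lipoprotein lipase Lpl (-5.22), myosin light chain kinase Mylk (-5.31), the guidance factor Sema3d (-5.07) and Lrrn4 (-5.50).

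Of 19 spermatogonial markers, 6 rose, 0 fell and 13 were not called, with a median difference of 1.73 that exceeded all of 10000 random lists matched on mean level. The transcription factors Sohlh1 (4.28) and Sohlh2 (2.81) and the stem cell factor receptor Kit (3.24) led them. Zbtb16, a factor of undifferentiated spermatogonia, differed by 1.67 and was not called. Of 15 piRNA pathway genes, which silence transposons in germ cells, 6 rose and 0 fell (median 1.39, 0.29 to 2.05 over lane pairings). Mael (4.28), the helicase Ddx4 (3.55) and Gtsf1 (2.47) showed the largest differences. Of 24 meiotic prophase genes, 4 rose, among them Tex11 (3.05) and Tex101 (2.95), and 0 fell (median 0.67, percentile 99.95). Over lane pairings this median was lower, at 0.18 to 0.62. Of 19 pachytene-to-spermatid genes, 2 rose, namely the testis linker histone Hist1h1t (2.89) and Tbpl1, a TATA-binding protein relative (3.57, but 1.09 summed over its transfrags). None of 27 spermatid genes and none of 24 flagellar axoneme genes was called, and their medians were 0.00 and -0.01.

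Sertoli markers were present in both preparations. Of 18 measured, 1 rose, 3 fell and 14 were not called, with a median of -0.30 (percentile 2.93). The iron carrier Tf (-4.66), the cystatin Cst12 (-2.73) and clusterin, Clu (-2.46), fell. Inha, the inhibin alpha subunit, rose by 2.21 from 16.6 to 80.6 FPKM. Wt1, a Sertoli cell transcription factor, was at 65.8 FPKM in Sertoli cells and 34.7 FPKM in the spermatogonial preparation (-0.90), and anti-Mullerian hormone, Amh, at 1.70 and 8.86 FPKM (1.87). Neither was called. Markers of further cell types moved as well. Of 6 peritubular myoid markers, 3 fell (median -2.10), including the smooth muscle actin Actg2 (-2.89) and Lmod1 (-2.28, but -1.69 in the tracks). Tagln stood at 2283 FPKM in the Sertoli preparation. Of 4 Leydig cell markers 1 rose, the steroid enzyme Cyp17a1 (2.92, to 7.01 FPKM). Of 5 macrophage and leukocyte markers 2 rose, Tyrobp (2.90) and lysozyme Lyz2 (2.04, under 4-fold in some pairings). Of 3 erythroid markers, the globins Hba-a2 (5.24) and Hbb-b1 (2.79) rose and the haem synthesis enzyme Alas2 (-4.21) fell. The 1 measured endothelial marker, Flt1, differed by -0.03.

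Of 19 extracellular matrix genes, 3 rose and 3 fell (median -0.98). The proteoglycan Dcn (3.42) and the collagen Col6a1 (2.64) rose, while the basement membrane collagen Col4a2 fell by 3.70 in its transfrag but differed by -1.37 when summed, under the rule. None of 18 genes of cholesterol and steroid synthesis was called, although their median of -0.80 lay at percentile 0.01. Of 26 mitotic cell cycle genes 0 rose and 1 fell, with a median of 0.60 at percentile 99.93. The fall was cyclin Ccnb2 (-2.40), whose summed transfrags gave 0.25, so its direction depended on the transfrag. The labels do not say how pure each preparation was, and without a second library per cell type these differences have no biological replicate check.

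The second comparison, pachytene spermatocytes against spermatogonia, covers entry into and progress through meiosis and showed the largest number of changes of the 3. Crisp2, a protein of the acrosome and tail, rose by 11.21 (11.11 to 11.30) to 2487 FPKM. Ldhc, the lactate dehydrogenase of male germ cells, rose by 9.84 (9.60 to 10.07) to 1114 FPKM. Among the falls were the intermediate filament vimentin, Vim, from 339 to 0.426 FPKM (-7.90, -7.98 to -7.82), and the X-linked ribosomal protein Rpl10 from 432 to 0.400 FPKM (-8.27, -8.35 to -8.19). In all 12305 transfrags rose and 10668 fell, 9834 and 7724 of them in every pairing of lanes, against 226 calls from lane differences.

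Among transfrags that match an annotated transcript the largest rise was that of Cmtm2a (11.62, to 3299.7 FPKM), followed by Crisp2 and the gene model vawmee (10.26). Cox8c, a testis subunit of cytochrome c oxidase (9.91), Fabp9, a lipid-binding protein of the sperm head (9.76), the LIM protein Fhl4 (9.65), the acrosomal protein Dkkl1 (9.41) and the histone reader Phf7 (9.29) came next. Large falls in the same class were those of the ribosomal protein gene Rps4x (-8.85), the actin-sequestering Tmsb4x (-7.90), the retinaldehyde dehydrogenase Aldh1a1 (-7.65), the matrix protein Sparc (-7.52) and the glutathione transferases Gstm2 (-7.47) and Gstm6 (-7.13). The assembly places the Rps4x and Tmsb4x transfrags on chromosomes 4 and 5, and the glutathione transferases are a gene family, so reads shared with copies leave these levels uncertain.

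Of 19 pachytene-to-spermatid genes 17 rose and 1 fell (median 6.64). The glycolytic enzyme Pgk2 rose by 7.40 to 179 FPKM. The fall was that of Tbpl1 (-3.97), which rose by 4.33 when its transfrags were summed, so its direction depended on the transfrag. Of 24 flagellar axoneme genes 21 rose and 0 fell (median 4.56). The largest were Ropn1l (9.16), the tektin Tekt1 (8.33) and the dynein assembly factor Dnaaf1 (8.22). Of 27 spermatid genes 20 rose and 0 fell (median 3.91). The nuclear proteins Prm1 (8.64) and Tnp2 (7.06) and the outer dense fibre protein Odf1 (8.11) led them, from the table's floor of 0.05 FPKM or near it. Prm1, Tnp2 and Odf1 stood at 418, 140 and 290 FPKM in pachytene spermatocytes, against 58518, 10115 and 22721 in round spermatids. Carry-over of round spermatids into the pachytene preparation could contribute to the rises of these genes and was not tested. The acrosomal protein Acrv1 rose by 3.91. Tnp1, which replaces histones in spermatids, differed by 0.34 in its annotated transfrag but by 9.08 when its transfrags were summed. Of 15 piRNA pathway genes 10 rose and 0 fell (median 3.23), led by the Argonaute protein Piwil1 (7.07, to 141 FPKM) and the Tudor proteins Tdrd6 (6.72) and Tdrd7 (5.06). Of 24 meiotic prophase genes 13 rose and 2 fell (median 2.19). Of the rises, Tex12 (2.06) differed by -0.24 when its transfrags were summed. Syce1, of the synaptonemal complex (5.87), and the meiotic cohesin Stag3 (4.58) rose, and Tex15 fell by 4.41. Sycp3, another synaptonemal protein, had no transfrag of the classes used for gene values, and its contained transfrags summed to 111 FPKM in pachytene spermatocytes. All 5 medians lay above at least 99.98% of matched random lists.

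Of 18 Sertoli markers 0 rose, 15 fell and 3 were not called (median -4.03), with Vim, Aard (-6.43) and Inha (-6.00) falling furthest, and Wt1 (-4.88) and Amh (-3.23) among them. Tf fell by 2.51 but rose by 3.46 when its transfrags were summed. Of 19 extracellular matrix genes 0 rose and 16 fell (median -4.40), including the basement membrane protein Nid1 (-6.17) and the collagen Col3a1 (-5.87). Both medians lay below all random lists. The spermatogonial preparation held Sertoli markers near their level in Sertoli cells, such as Cldn11 at 74.8 against 90.9 FPKM, and others well below it, such as Tf. Falls in these 2 lists therefore cannot be told apart from a smaller share of somatic cells in the pachytene preparation. Of 19 spermatogonial markers 2 rose and 8 fell (median -1.75, percentile 0.04). The integrin Itga6 (-6.70) and the cyclin Ccnd2 (-6.41) fell, and Dmrtb1, a regulator of the switch to meiosis, rose by 7.14. Kit (-1.86) and Zbtb16 (-1.59) were not called. Dazl, which is on none of the lists, fell by 2.69. Of 26 mitotic cell cycle genes 1 rose and 7 fell (median -0.13, percentile 46.8), with the replication helicase subunits Mcm2 (-5.37), Mcm4 (-4.91) and Mcm6 (-4.31) showing the largest falls. Of 18 cholesterol and steroid genes 2 rose (1 of them differed by -1.70 when its transfrags were summed) and 6 fell (median -1.35, percentile 4.18), among them the desaturase Scd (-6.44).

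Markers of other cells moved with these groups. Of 6 peritubular myoid markers 3 fell, namely Myl9 (-6.02), Tagln (-5.39) and desmin, Des (-3.01). Of 4 Leydig markers 2 fell, Cyp17a1 (-2.92) and Hsd17b3 (-2.83), and of 3 erythroid markers 2 fell, Hba-a2 (-5.05) and Hbb-b1 (-2.79). Of 5 macrophage and leukocyte markers 2 fell, Tyrobp (-2.90) and Cd14 (-2.60), and 1 rose, Aif1 (3.53). Flt1 differed by 1.23 and was not called. The balance of rises and falls depended on how the values were computed, and scaling alone was not varied. Rises made up 53.6% of calls in the deposited values and 37.3% in values recomputed from the coverage tracks, where the median transfrag differed by -0.77 (-0.08 as deposited).

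**Figure D2:**
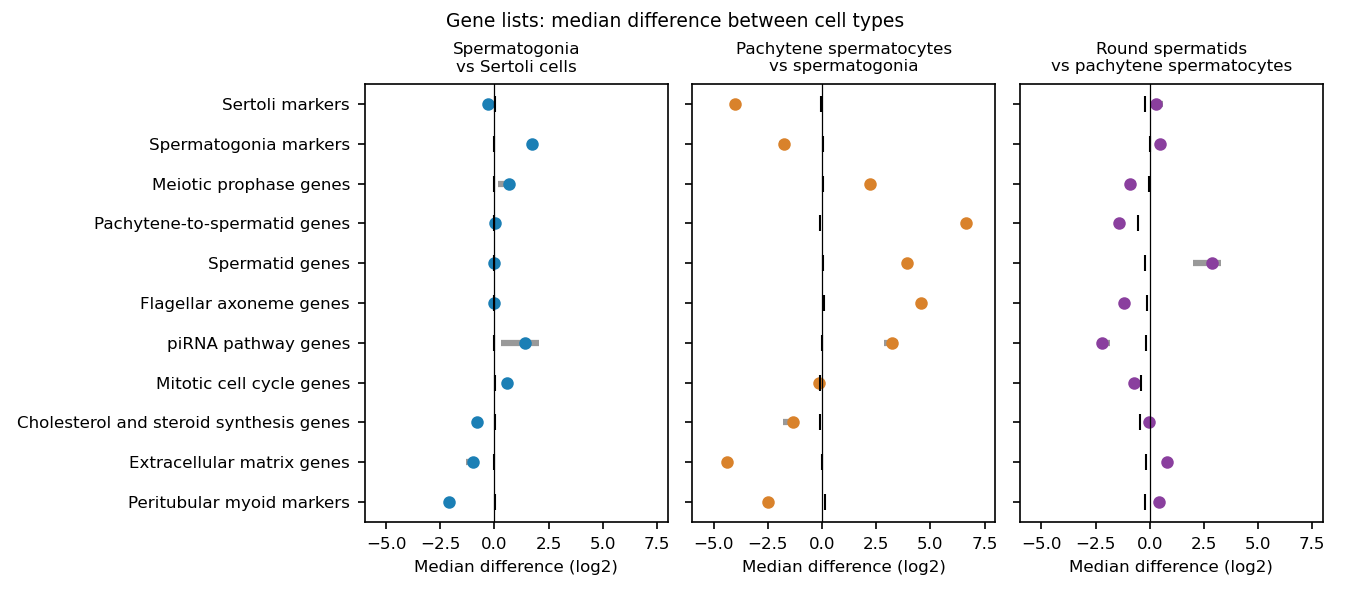
Median log2 difference of the members of 11 gene lists (rows) in the 3 comparisons (panels). Points are medians of lane means, grey bars span the medians of the 4 lane pairings and black ticks mark the median of matched random lists, so that the pachytene-to-spermatid genes stand at 6.64 in the middle panel.

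The third comparison, round spermatids against pachytene spermatocytes of the same age, covers the completion of meiosis. Of 27 spermatid genes 15 rose, and of 15 piRNA pathway genes 8 fell. The protamines, which package sperm DNA, rose by 7.12 (Prm1, 7.01 to 7.24) and 7.11 (Prm2, 7.01 to 7.22), and Prm1 reached 58518 FPKM. Hist1h1t fell by 5.93 (-6.08 to -5.78) from 1254 to 19.6 FPKM, and Piwil1 by 4.37 (-4.40 to -4.33) from 141 to 5.86 FPKM. In all 6501 transfrags rose and 5505 fell, 4731 and 3326 of them in every pairing of lanes, against 393 calls from lane differences.

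Serpina1, a serine protease inhibitor, had the largest rise of an annotated gene (7.45, to 5068 FPKM). The spermatid kinase Tssk6 (6.90), the calcium-binding Cabs1 (6.75), Spem1, required for spermatid maturation (6.66), Fam71f2 (6.42) and the carbonic anhydrase Car2 (6.08) rose as well. Pgk2 rose by 3.14 to 1591 FPKM, and Tnp1 by 3.61 in its annotated transfrag and 5.71 summed. Ldhc (-1.10) and Acrv1 (1.10) were not called. Among the falls were Pcbp3, which binds poly(C) RNA (-4.98), the chaperone Hyou1 (-4.97), the zinc finger gene Zfp646 (-4.63), the reductase Akr1e2 (-4.45) and the gene model steedor (-4.86). The mRNA export genes Fyttd1 (-4.93, -6.51 to -3.35) and Thoc7 (-4.36, -5.98 to -2.73) fell with wide lane ranges. Summed over their transfrags, Pcbp3 (-1.42) and Akr1e2 (-1.62) no longer reached 4-fold.

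Of the spermatid genes 0 fell and 12 were not called (median 2.90, above all random lists). Of the piRNA pathway genes 0 rose and 7 were not called (median -2.22, below all random lists), and those that fell included Pld6 (-3.37) and Tdrd5 (-3.00). Of 24 flagellar axoneme genes 1 rose, Ropn1 (5.42), and 6 fell, among them Tekt1 (-2.62) and Spag16 (-2.54), with a median of -1.21 (percentile 0.16). Of 19 pachytene-to-spermatid genes 2 rose and 7 fell, including the cyclin kinase subunit Cks2 (-4.53), with a median of -1.43 (percentile 0.83). Of the rises, Tbpl1 (2.25) fell by 3.14 when its transfrags were summed. Of 24 meiotic prophase genes 4 rose, Tex15 among them (2.72), and 3 fell. Of those that fell, the break-forming enzyme Spo11 (-2.90) and the bridge protein Tex14 (-2.51) did not reach 4-fold in every lane pairing or when summed. The median of this list was -0.89 with 1 transfrag per gene and 0.13 with transfrags summed, so its direction is not settled.

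Of 26 mitotic cell cycle genes 0 rose and 5 fell (median -0.72, percentile 19.4), led by the anaphase activator Cdc20 (-3.93), the replication clamp Pcna (-2.58) and the kinase Cdk1 (-2.54). Of 18 cholesterol and steroid genes 1 rose, the sterol demethylase Cyp51 (4.06, to 144 FPKM), and 0 fell (median -0.04, percentile 81.4). Of 19 spermatogonial markers 4 rose, including the retinoic acid target Stra8 (3.35) and the hydrolase Uchl1 (2.11), and 2 fell, including Id4 (-2.54, under 4-fold in some pairings), with a median of 0.49 (percentile 93.6). None of 18 Sertoli markers was called (median 0.31, percentile 90.4), and of 19 extracellular matrix genes 1 rose, the protease inhibitor Timp2 (2.39, but 1.72 summed). Of 6 peritubular myoid markers 1 rose, Actg2 (3.64, to 14.8 FPKM), and of 4 Leydig markers 1 rose, the hormone receptor Lhcgr (3.30, to 9.52 FPKM). Of 5 macrophage and leukocyte markers 3 rose, Aif1 (4.32, to 268 FPKM), Lyz2 (3.48) and Cd74 (2.44). No erythroid marker was called, and Flt1 differed by 0.42. Rises made up 54.1% of calls in the deposited values and 28.3% in values from the tracks, where the median transfrag differed by -0.21 (0.00 as deposited).

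X-linked transfrags were compared with autosomal ones because the X chromosome is silenced in pachytene spermatocytes. From spermatogonia to pachytene spermatocytes the median change of 2192 X-linked transfrags minus that of 77370 autosomal ones was -1.46 (95% bootstrap interval -1.53 to -1.38 over transfrags, which are not independent). It lay below all of 10000 matched random sets. Of the X-linked transfrags 36.2% (793) fell and 54 rose, while 12.6% of autosomal ones fell. Among annotated X-linked transfrags 175 of 319 fell and 20 rose. In the unnormalized tracks the X share of exonic fragments was 3.40% in Sertoli cells, 3.01% in spermatogonia, 0.307% in pachytene spermatocytes and 1.83% in round spermatids. From pachytene spermatocytes to round spermatids 289 X-linked transfrags rose and 15 fell, and 68 and 1 of the annotated ones did. In the deposited values the median exceeded the autosomal one by 0.45 with both lanes. It did so by 0.33 without lane 2 of the round spermatids and by 0.00 without lane 1, so its size was not stable. Leaving out a lane also changed which transfrags passed the filter, so the change cannot be assigned to the lane alone. In values from the tracks, with both lanes, the difference was 0.47. Between spermatogonia and Sertoli cells the difference was 0.00, yet 154 X-linked transfrags rose and 73 fell (7.03% rose, against 3.61% of autosomal ones), and 18 and 10 of the annotated ones did.

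**Figure D3:**
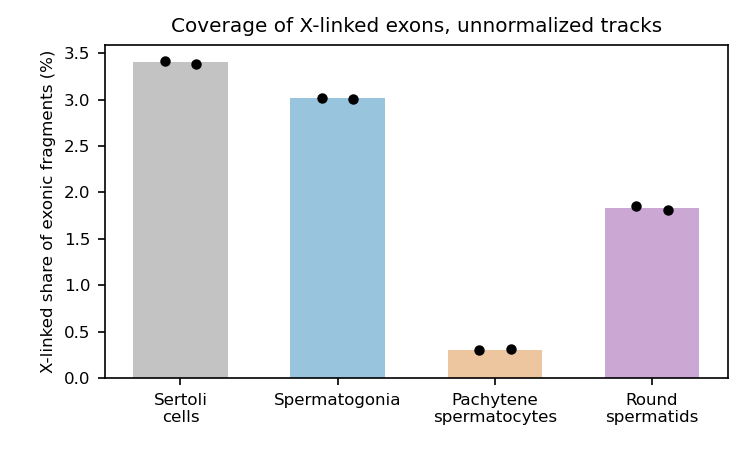
Percent of exonic fragments that fell on X-linked exons in the unnormalized coverage tracks, without chrUn and chrM. Bars are means of the 2 lanes, shown as points, and stand at 3.01% in spermatogonia and 0.307% in pachytene spermatocytes.

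The assembly allowed transcribed regions outside annotated genes to be compared with annotated transcripts. Of its transfrags 10541 matched an annotated transcript, 27279 were new isoforms of annotated loci, 23947 lay within introns, 9237 were intergenic and 1404 overlapped an exon on the other strand. Of 7832 compared intergenic transfrags 53.7% differed between cell types (95% Wilson interval 52.5 to 54.8), against 66.2% (65.2 to 67.1) of 9706 annotated ones. That order depended on the settings, since with a pseudocount of 0.1 the shares were 98.8% and 85.6%, and with at least 2 exons 73.9% and 66.2%. The highest level was in pachytene spermatocytes or round spermatids for 70.6% of the differing intergenic transfrags and 46.4% of the annotated ones. In values from the tracks these shares were 53.8% and 38.3%. With at least 2 exons, the intergenic share was 95.6% of 1365 transfrags. New isoforms (74.1%) and antisense exonic transfrags (88.7%) also peaked in these cells, whereas 44.6% of differing intronic transfrags were highest in Sertoli cells and 36.6% in spermatogonia. The kit did not mark strand, so the 1219 of 1404 antisense transfrags with more than 1 exon rest on the strand of spliced reads, the source of strand for the others is not given in the sources used here, and intronic ones cannot be told from unspliced RNA. Reads over bases that an antisense transfrag shares with the overlapped gene cannot be assigned to either strand. The cell type of its highest level may therefore be that of the overlapped gene. Intervals cover counting error only.

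**Figure D4:**
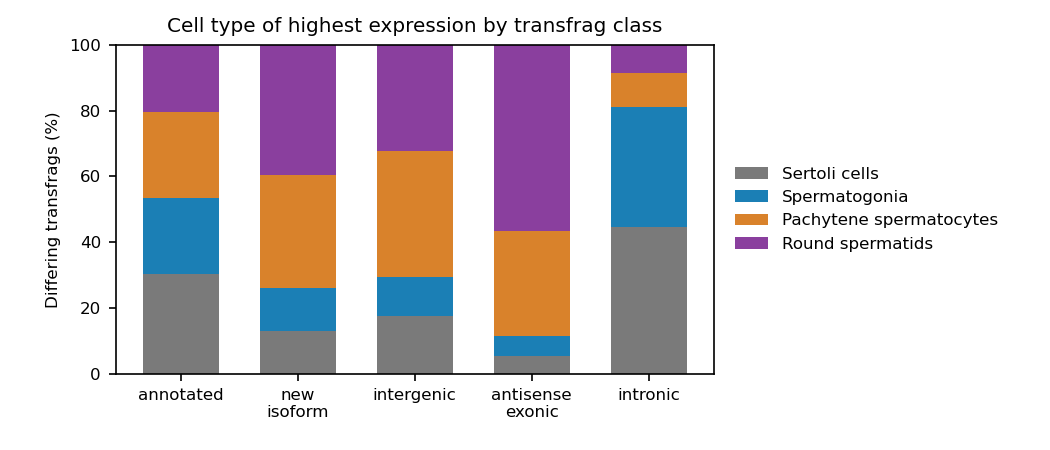
Percent of differing transfrags whose highest level was in each cell type, for 5 classes of transfrag. Pachytene spermatocytes and round spermatids together held 46.4% of annotated, 70.6% of intergenic and 88.7% of antisense exonic transfrags. Levels of antisense exonic transfrags can include reads of the overlapped gene, as strand was not marked.

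Multi-exon intergenic transfrags at least 4-fold above every other cell type numbered 9 in Sertoli cells, 5 in spermatogonia, 143 in pachytene spermatocytes and 585 in round spermatids. Coordinates are those of rat assembly rn4. In round spermatids the highest levels were those of a 2-exon transfrag on chromosome 6 from 7879214 to 7880825 (277.7 FPKM) and a 6-exon transfrag on chromosome 1 from 186149397 to 186152728 (253 FPKM, 7588 fragments in both lanes). In pachytene spermatocytes 2 overlapping isoforms of 1 locus on unplaced sequence, from 42639217 to 42666675 and from 42641403 to 42670593, reached 287 and 169 FPKM. Spermatogonia expressed a 2-exon transfrag on chromosome 17 from 48785611 to 48787913 at 83.3 FPKM and another on chromosome 5 from 108513959 to 108527164 at 13.7 FPKM. In Sertoli cells a 15-exon transfrag on unplaced sequence from 15074413 to 15124615 stood at 27.2 FPKM and a 4-exon one from 5903067 to 5911837 at 25.5 FPKM. Fragments over their exons in both lanes were 1989 in Sertoli cells and 797 in spermatogonia for the first, and 501 and 193 for the second. At near-equal exonic depth these lay under 4-fold. By their class code these transfrags lie between annotated genes. Leaving out unplaced and mitochondrial sequence left the annotated shares unchanged, at 66.2% differing and 46.4% of those highest in meiotic or later cells. No annotated transfrag there thus entered the comparison, so the class code of those on unplaced sequence may reflect missing annotation.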

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

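Among the tests in this part, those of the quantile normalization for the X chromosome, of the deeper pachytene library and of Sertoli cells were chosen after the result was seen.

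A large signal lay in sequence that the comparisons use little, with no control sample to set it against. Of mapped bases 56.2% in Sertoli cells, 57.8% in spermatogonia, 47.9% in pachytene spermatocytes and 70.1% in round spermatids fell on unplaced sequence. It covered 0.683 to 1.77 megabases there, and 0.264% to 0.624% of those bases lay in assembled exons.

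X-linked transfrags were lower in pachytene spermatocytes than in spermatogonia (median difference from autosomal -1.46). The tables argue against the authors' quantile normalization, since the X share of exonic fragments in the unnormalized tracks was 0.102 times that of spermatogonia (0.101 to 0.103 over lane pairings). They argue against a few abundant loci too, because without the 10 X-linked loci of highest coverage in spermatogonia the ratio was 0.0737. Meiotic silencing of the X chromosome may account for the pattern, as a hypothesis. The age of the animals (9 against 90 days) and somatic cells in the spermatogonial preparation stay open and were not tested.

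Multi-exon intergenic transfrags peaked in pachytene spermatocytes or round spermatids in 95.6% of 1365 cases. Quantile normalization does not account for this, since the share was 86.6% in values from the tracks, against 38.9% for annotated multi-exon transfrags. Low expression and transcript length account for part of it at most, since matching on mean level and length raised the annotated share from 46.9% to 65.6%, against 95.7% for the intergenic ones with a match. Round spermatids, with less exonic depth than pachytene spermatocytes, held 13.9 times as many (835) as Sertoli cells and spermatogonia together (60). This count cannot decide whether the deeper pachytene library contributed. In the combined assembly a transfrag found through pachytene reads can still be highest in round spermatids. Pachytene exonic depth was 1.71 times that of spermatogonia, and the assembly could not be repeated at equal depth. The deeper library therefore remains a possible explanation for these 835 and for the 470 highest in pachytene spermatocytes. Whether the reference annotation holds fewer germ cell transcripts was not tested.

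Sertoli markers were present in the spermatogonial preparation, with a median difference of -0.30 from Sertoli cells. Carry-over of Sertoli cells like those of the 20-day preparation would keep each marker at or below its level there, if that preparation were pure. Yet 3 of the 16 markers at 1 FPKM or more in both (Amh, Inha and Fshr) were over 2-fold higher in every lane pairing. The 20-day preparation also held the myoid marker Tagln at 2283 FPKM, so its purity is not settled. These 3 markers cannot exclude such carry-over for the others. Differences over the 18 markers ran from -4.66 to 2.21. Carry-over of Sertoli cells of the 9-day animals, which may differ from older ones, and expression by the germ cells themselves cannot be told apart, since none of the 8 samples holds Sertoli cells of that age.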

How the results depend on the processing

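No paired analysis was possible because the 2 samples of a cell type were counted as lanes of 1 library and no test was run. For the same reason the fits with and without a variance trend were not run. Leaving out unplaced and mitochondrial sequence, and keeping transfrags of at least 2 exons, was chosen after the data were seen. Of 270 values of the main results under alternatives 202 stayed within their bounds (1.5 times for counts, the 95% interval for shares and X-linked differences), and none changed sign, which counts and shares cannot. The order of rises and falls turned over in 3, 4 and 3 of 16 alternatives in the 3 comparisons, and that of the differing intergenic and annotated shares in 2 of 15. The causes of the other changes were not tested, except where the construction sets them: a lower pseudocount or threshold calls more transfrags, and 1 value per locus compares fewer.

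With a pseudocount of 0.1, rises and falls numbered 11289 and 11447 (spermatogonia against Sertoli cells), 24565 and 24750 (pachytene spermatocytes against spermatogonia) and 12783 and 16491 (round spermatids against pachytene spermatocytes). In all 75197 differed, 21317 highest in Sertoli cells, 19406 in spermatogonia and 19857 in pachytene spermatocytes. The X-linked difference was -3.39 in the second comparison and 1.11 in the third. Of annotated and intergenic transfrags 85.6% and 98.8% differed, and 58.9% of the latter were highest in meiotic or later cells.

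Without a filter the X-linked differences were -1.06 and 0.31, and 61.0% of annotated and 45.6% of intergenic transfrags differed. With the filter at the table's median the second X-linked difference was -1.33, and the shares were 64.7% and 50.4%. With 1 value per locus, rises numbered 1912, 7190 and 3562 in the 3 comparisons and falls 2902 in the third. Then 26671 loci differed, 6355 highest in pachytene spermatocytes and 5635 in round spermatids, and the X-linked differences were -1.36 and 0.51. Of annotated loci 64.8% differed, and 48.4% of annotated and 67.7% of intergenic ones peaked in meiotic or later cells.

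From the tracks, 1814 rose and 1928 fell in the first comparison, 12117 and 20328 in the second and 4974 and 12612 in the third. The highest level was in Sertoli cells for 21281, in spermatogonia for 20101, in pachytene spermatocytes for 15048 and in round spermatids for 8176. Of annotated transfrags 80.6% differed (38.3% of them highest in meiotic or later cells), and of intergenic ones 57.6% (53.8%). At a threshold of 1, rises and falls were 13411 and 13647, 24925 and 25537, and 13607 and 18128, and 77237 differed. At 4 they were 266 and 175, 2270 and 1625, and 1010 and 349, and 8634 differed. Without unplaced and mitochondrial sequence 72.4% of differing intergenic transfrags peaked in meiotic or later cells. Of intergenic transfrags with at least 2 exons 73.9% differed and 95.6% of those peaked there.

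Leaving out each lane in turn gave X-linked differences of 0.00 to 0.048, -1.50 to -1.35 and 0.00 to 0.45 in the 3 comparisons, and 68.9% to 71.2% of differing intergenic transfrags highest in meiotic or later cells. The third X-linked difference was 0.00 without lane 1 of the round spermatids.

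Of 420 medians of gene lists 316 moved by less than their lane spread. The meiotic prophase genes in the third comparison went from -0.89 to 0.13 with transfrags summed. Of 579 values of named genes under alternatives, 196 were counted as unchanged, 382 as moved and 1 as reversed, so sizes of single genes depended on the processing. Of 140 gene differences past 4-fold, 9 no longer were with transfrags summed, 5 from the tracks and 0 with a pseudocount of 0.1. Ccnb2 in the first comparison went from -2.40 to 0.25 when summed. Of 252 calls of list members 6 changed sign when summed, those of Tbpl1 and Tf in the second comparison and Tbpl1 in the third among them. Little can be said of weak transcripts, since 24.7% to 48.2% of each sample's values lay at the table's floor. That share did not follow exonic depth. At the floor in both lanes were 28.3% of transfrags in pachytene spermatocytes, the deepest in exons, and 36.2% in round spermatids. Sertoli cells and spermatogonia had 18.3% and 17.2%.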

Other observations

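The X-linked genes in this part were chosen after their values were seen. Of 289 annotated X-linked symbols 65 rose from pachytene spermatocytes to round spermatids and 1 fell. Among named genes the highest level in round spermatids was that of Akap4, the main anchoring protein of the sperm fibrous sheath, which rose by 5.50 from 13.8 to 668 FPKM and was at the table's floor in Sertoli cells and spermatogonia. Actrt1, an actin-related protein of the sperm head, rose by 4.34 to 121 FPKM, and Ppp1r2-ps1 by 4.57 to 164 FPKM. Genes with the largest X-linked falls in pachytene spermatocytes stayed far below their spermatogonial level in round spermatids. Rpl10 reached 8.76 FPKM against 432 and Maged1 3.75 against 237. The chromatin protein Rbbp7 reached 5.19 against 153 and the cold-induced RNA-binding protein Rbm3 3.46 against 99.4. In Sertoli cells these genes stood at 356, 331, 197 and 99.6 FPKM in that order. Somatic cells in the spermatogonial preparation could therefore contribute to these gaps, which was not tested. The 1 symbol that fell from pachytene spermatocytes to round spermatids was a short transfrag named Prkar1a (-2.42), on the X chromosome from 148642197 to 148642454. It has 1 exon, and reads shared with copies elsewhere were not traced, so this fall is uncertain.

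The share of mapped bases in assembled exons, without chrUn and chrM, was 57.3% in Sertoli cells and 57.1% in spermatogonia, against 79.9% in pachytene spermatocytes and 75.4% in round spermatids. The genome covered by at least 1 read fell in the same order of cell types, from 154 megabases in Sertoli cells and 135 in spermatogonia to 86.5 in pachytene spermatocytes and 42.9 in round spermatids. Of differing intronic transfrags with at least 2 exons, 92.1% of 483 peaked in pachytene spermatocytes or round spermatids, against 18.8% of all 8702 differing intronic transfrags.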
